A study of Mus musculus with 12 samples.

How the data were processed

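Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 12 libraries of B16F10 mouse melanoma cells. Groups were taken from the submitters' sample labels: cells transduced with a guide RNA against the neutral Rosa26 locus (sgRosa26, TRAF3-replete) or with either of 2 guides against Traf3 (sgTraf3-1 and sgTraf3-2, TRAF3-deficient), treated for 2 days with vehicle or with IFNγ at 1 ng/ml. Each of the 6 groups had 2 libraries. The labels' protocol speaks of triplicates, and no label says whether libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

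The deposited values were 1 peak list per library, holding chromosome, start, end, a peak name and a score. Mapping to mm10 with BWA and peak calling with MACS2 are named in the submitters' processing notes, which also name DESeq2, without versions, parameters or roles. The score that the authors' caller gave each peak was read as a −log10 p-value or q-value, since the lowest score in each of the deposited lists lay just above 2.0; which of p and q it is, any read filtering, and the Tn5 offset are not given in the sources used here. Replicates were not pooled in these lists. Read depth was unknown, so the length of a list and the significance of its peaks cannot be corrected for depth. The score was used to rank peaks within a list. It was compared across lists only in an alternative count of peaks, which this unknown depth also limits.

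The lists held 11387 to 27623 peaks, 227701 in all. Because a longer list calls more regions whatever the biology, each list was shortened to its 11387 highest-scoring peaks, the length of the shortest list. This kept 41.2% to 100% of a list, and the score at the limit ranged from 2.01 to 15.7. The limit therefore fell at different depths of the lists, and a region not called lay below the limit in that library and was not shown to be closed. Peaks of all 12 full lists were merged where they overlapped by at least 1 bp, and the 27731 merged regions called in at least 2 lists were kept (median width 768 bp). A region counted as called in a library if at least 1 bp of it overlapped a peak of the shortened list. Regions were assigned to the gene with the nearest annotated end, within 50 kb, among 21905 genes of the RefSeq table for GRCm38.p6, the assembly behind mm10. These were the protein-coding genes and the list genes, so a distance to a gene end leaves other annotated genes out of account. The table gives the start and end of each gene without its strand, so either end was used in place of the transcription start site that had been planned, and exons, introns and untranslated regions were not told apart. Of the regions, 22748 (82.0%) lay within 50 kb of a gene end. Coordinates are those of mm10, counted from 1.

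A region was called separated when all libraries of one group and none of the other called it. Regions called in the first-named condition are termed gained and those called in the other lost. The number of separated regions was set beside that of other splits of the same libraries into groups of the same sizes, all of them or 100 drawn at random, the real split included. The p-value of a single separated region came from Fisher's exact test, two-sided. The number of called regions near the genes of 11 lists (365 genes, each found in the gene table) was compared by exact permutation of the treatment within guide (216 arrangements, smallest possible p 0.00926) or of the genotype within treatment (225 arrangements, smallest possible p 0.00444), two-sided, with Benjamini-Hochberg adjustment over 33 tests. The test of whether the IFNγ effect differed between genotypes permuted the genotype within treatment, and so tests against no effect of genotype of any kind. Each list's difference was also placed among 10000 random gene lists matched on the number of regions per gene. Enrichment of a list among separated regions was tested by Fisher's exact test against the other regions called in as many libraries and within 50 kb of a gene end, adjusted over 154 tests. The background counts printed with it include the separated regions, and the test treats neighbouring regions as independent. The similarity of libraries was measured by the Jaccard index, the regions called in both libraries over those called in either, with a one-sided permutation test.

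The lists covered MHC class I and class II antigen presentation, interferon response, checkpoint ligands, NF-κB pathway components, NF-κB target genes, melanocyte lineage, dedifferentiation and AP-1, leukocyte markers, skin and stroma markers, and housekeeping genes. They, the main tests, most alternatives and the rule for naming genes were fixed before the data were examined. Not among the planned tests were the enrichment of lists among separated regions and the overlap of separated regions between genotypes. The adjustment over a single list was not planned either. The rule named Traf3, each list gene with a separated region in the comparison of treatments or of genotypes, up to 10 further genes per direction with the most separated regions (ties decided by the smallest median rank), and B2m, H2-K1, H2-D1, Cd274, Tap1, Irf1, Nfkb2, Relb and Birc3. One further gene named by the rule is not reported here. Other genes named were chosen after their values were seen.

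Alternatives were the authors' full lists, the top 5693 peaks of each list, a 50% overlap of peaks narrowed to 200 bp, up to 1 exception per group of 4 or more libraries, per-region tests with adjustment, assignment within 1 kb of a gene end, a replicate block, and each library left out. For peak numbers, a common score threshold of 15.7 was also applied to every list. One more, the 9 longest lists shortened to 17482 peaks, was chosen after seeing the data. The planned search for transcription factor motifs was not run, since no genome sequence was used here. Calling was tested on simulated data with 200 changed regions among 27731. With changed regions called at a rate of 0.95 in one group and 0.05 in the other, complete separation recovered 56.0% of them for 6 against 6 libraries, 66.5% for 4 against 4 and 56.5% for 8 against 4. With rates of 0.8 and 0.2 it recovered 11.5%, 14.0% and 5.0%. At the first rates, 1, 36 and 5 regions that had not been changed were also separated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.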

Results

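Accessible chromatin was mapped in B16F10 cells, a mouse melanoma line, with and without TRAF3 and with and without IFNγ. TRAF3 is an adaptor that restrains non-canonical NF-κB signalling by keeping the kinase NIK (Map3k14) at low levels, and IFNγ is a cytokine that induces antigen presentation. The series title concerns the separation of MHC class I from PD-L1 expression. The comparisons below ask which regions were called open after IFNγ, after loss of TRAF3, and with both. The 12 peak lists held 20812 ± 4530 peaks after vehicle (SD, n = 6) and 17138 ± 4169 after IFNγ (SD, n = 6), a difference of -3674 that did not exceed the spread between libraries (exact permutation test, p = 0.222). The sgTraf3 lists held 18868 ± 4068 peaks (SD, n = 8) and the sgRosa26 lists 19189 ± 6161 (SD, n = 4; exact permutation test within treatment, p = 0.916). Among the 11387 strongest peaks of each list, 37.5% to 41.6% had their centre within 1 kb of a gene end. That share was 40.6% ± 0.941 after IFNγ and 39.5% ± 1.62 after vehicle (SD, n = 6 each; exact permutation test, p = 0.222), and the genotype difference was 0.476 percentage points (exact permutation test, p = 0.573).

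At Traf3 itself, a region 460 bp from the gene's end (chromosome 12, 111164191 to 111165861) was called in all 12 libraries. Another, 22217 bp from the gene's end (111142670 to 111144104), was called in 2 of 2 sgRosa26 and 0 of 4 sgTraf3 libraries after IFNγ. Over both treatments it was called in 4 of 4 and 2 of 8 (Fisher's exact test, p = 0.0606), and the full lists held it in 11 of 12 libraries. The knockout itself was not checked by the peak lists. Regions at B2m, which encodes the invariant light chain of MHC class I (chromosome 2, 122146871 to 122148878), at Relb (chromosome 7, 19628314 to 19629188) and within Nfkb2 (chromosome 19, 46304202 to 46305836), the latter pair encoding subunits of the non-canonical NF-κB pathway, were also called in all 12. No region was assigned to Birc3, which encodes a ubiquitin ligase of the TRAF complex.

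After IFNγ, over all guides, 36 regions were called in 6 of 6 IFNγ libraries and 0 of 6 vehicle libraries, and 2 regions showed the converse. Of the gained regions, 9 belonged to the interferon response list. Immunity-related GTPases, which act against intracellular pathogens, supplied regions at Irgm1 (chromosome 11, 48870954 to 48872685), Tgtp1 (48993964 to 48994506), Ifi47 (49081369 to 49082005), Igtp (58199235 to 58200182) and Irgm2 (58214367 to 58215457), all on chromosome 11. The guanylate-binding protein genes Gbp7 (chromosome 3, 142529624 to 142530549) and Gbp3 (142559539 to 142560920) each gained a region at a gene end. So did Mx2, an antiviral GTPase gene (chromosome 16, 97534869 to 97536337), and Ifit3b, of the family of interferon-induced proteins with tetratricopeptide repeats (chromosome 19, 34607287 to 34607931). Tgtp1 has a near-identical neighbour, Tgtp2, whose own end was called in 5 IFNγ and 0 vehicle libraries (Fisher's exact test, p = 0.0152); reads shared between them leave the assignment uncertain.

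Within the MHC class I list, 2 regions were gained over all guides. One spanned the shared end of Psmb9, an immunoproteasome subunit gene, and Tap1, which encodes a subunit of the peptide transporter (chromosome 17, 34187104 to 34188081). The other lay 2744 bp from H2-T24, a non-classical class I gene (chromosome 17, 36023544 to 36024336). Outside the lists, gained regions lay nearest to Gvin1, a very large interferon-inducible GTPase gene (chromosome 7, 106236063 to 106237525, 20723 bp from its end). Its median rank in its lists was 58.5, the strongest among the separated regions of the genes named by the rule. Further ones lay at Parp11 (chromosome 6, 127446311 to 127447249), within Zc3hav1, which encodes the zinc-finger antiviral protein ZAP, near Apol6, at Tmem140 (present in 6 of 6 full vehicle lists), within Prkcq and Exog, near Tlnrd1 and Rbbp6, and 31859 bp from Nelfa inside Nsd2. Of the 36 gained regions, 10 lay within 1 kb of a gene end and 8 more than 50 kb away. The lost regions lay 38313 bp from Nol10 and 118638 bp from Meis1.

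**Figure D1:**
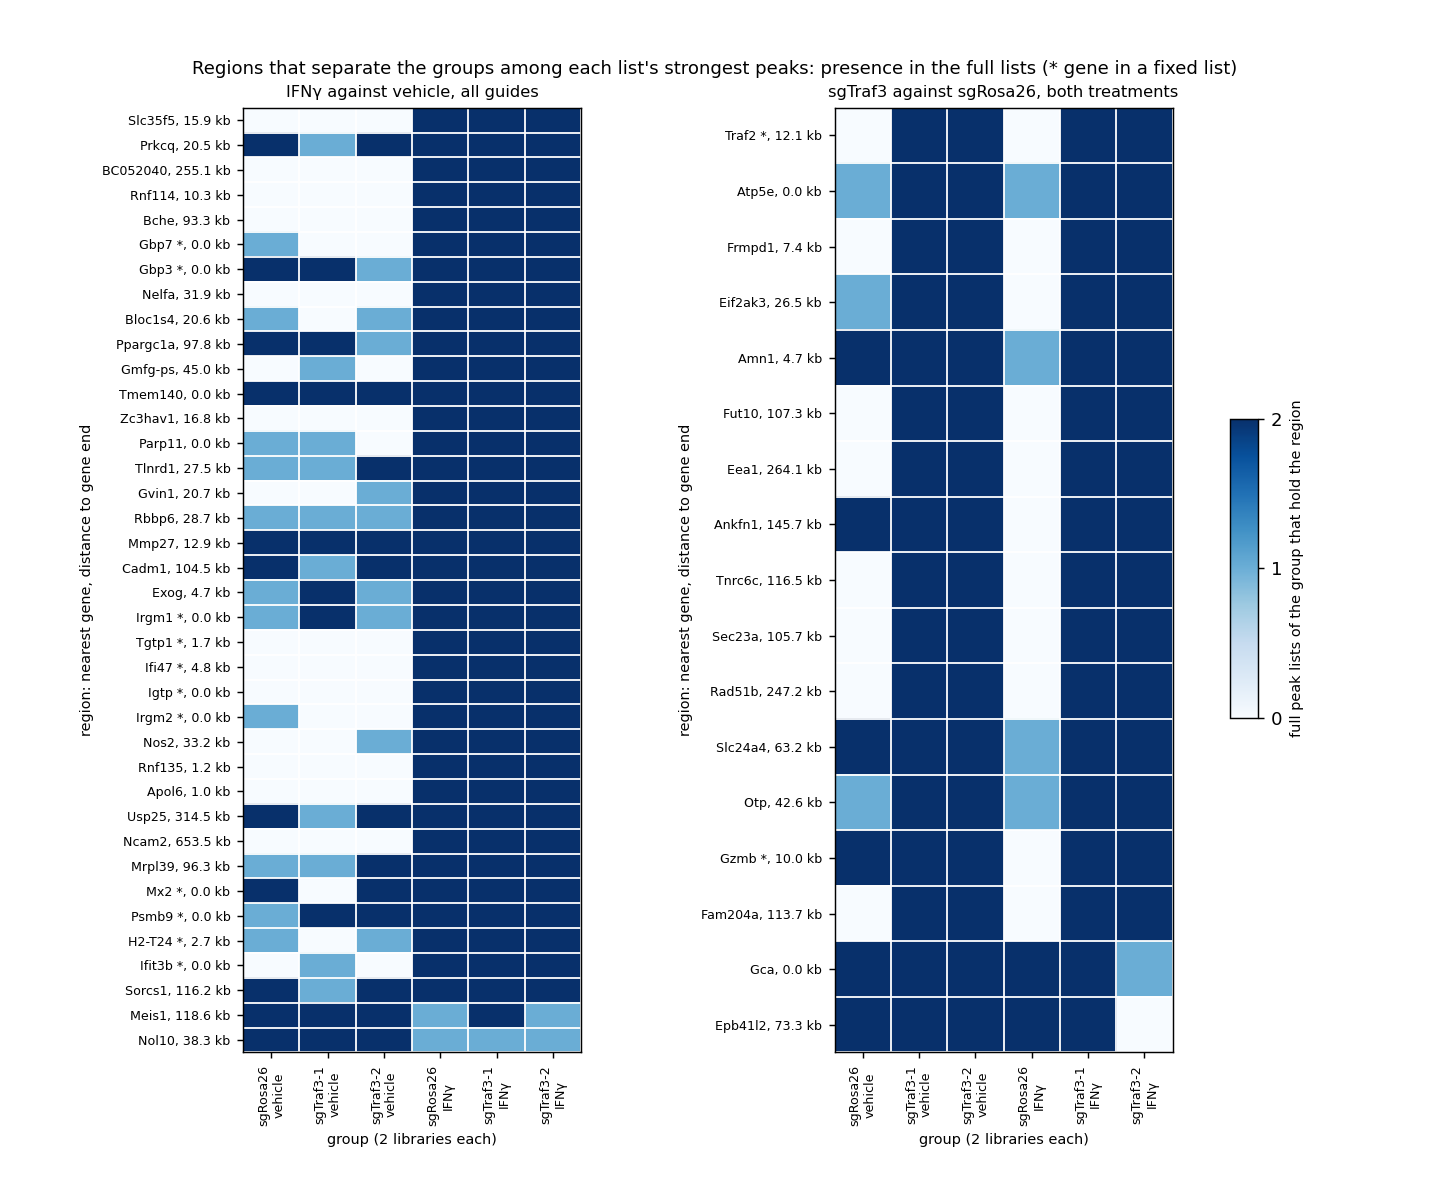
Each row is a region that separated the groups completely, named by its nearest gene and its distance in kb to that gene's end (* marks genes of a fixed list); columns are the 6 groups and the shade gives how many of a group's 2 authors' full lists hold the region. Of the 36 regions gained after IFNγ (left), 12 are absent from all vehicle lists, and of the 15 gained in sgTraf3 cells (right), 8 are absent from all sgRosa26 lists.

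Interferon response genes made up 9 of the 28 gained regions within 50 kb of a gene end. Among all regions called in as many libraries, these 28 included, they made up 12 of 656 (Fisher's exact test, adjusted p = 1.84e-09). Several of these genes are neighbours, so their regions may not be independent. For MHC class I genes the counts were 2 of 28 and 3 of 656 (Fisher's exact test, adjusted p = 0.132). A single region called in 6 of 6 against 0 of 6 libraries has p = 0.00216 (Fisher's exact test). Over the 4090 regions tested, 0 passed with Benjamini-Hochberg adjustment and 123 had an unadjusted p under 0.05. Adjusted over the list alone, 12 of 31 interferon response regions and 2 of 11 MHC class I regions passed. In the authors' full lists 19 regions were gained and 13 lost, and of the regions above 12 gained and 0 lost were separated there too. The 12 included those at Tgtp1, Ifi47, Igtp, Zc3hav1 and Apol6, while the regions at Psmb9 and Gbp3 were each present in 5 full vehicle lists. With the 9 longest lists, an alternative chosen after seeing the data, 102 regions were gained and 33 lost, 18 and 0 of them shared with those above.

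Counted per library, regions called near interferon response genes numbered 37.7 ± 3.08 after vehicle and 60.2 ± 4.40 after IFNγ (SD, n = 6 each), with 54 to 66 in every IFNγ library and 35 to 43 in every vehicle library. Of the list's 57 genes with a region, 42 had more calls after IFNγ, 6 fewer and 9 as many. MHC class I calls numbered 9.17 ± 1.47 and 17.5 ± 2.43 (SD, n = 6 each), with 12 of 22 genes higher, 0 lower and 10 equal. Among the genes of these lists Irf9, part of the interferon-activated transcription factor complex, was called at its end in 6 IFNγ and 1 vehicle libraries and Irf1 in 5 and 0 (Fisher's exact test, p = 0.0152 each). The corresponding counts were 5 and 2 at H2-D1 (Fisher's exact test, p = 0.242), and 4 and 0 at each of Psmb10 and the class I transactivator gene Nlrc5 (Fisher's exact test, p = 0.0606). Another region of Irf1 was called in all 12 libraries. Both list differences, 22.5 and 8.33 regions, gave the smallest p the exact permutation test allows, 0.00926, and exceeded each of 10000 random lists. The adjusted p of 0.102 over 33 tests did not pass; over the 11 lists of this comparison, an adjustment chosen after seeing the data, it was 0.034. With the full lists the differences were 14.5 and 6.0 regions, which did not pass (exact permutation test, p = 0.176 and 0.0556).

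Among the other lists, NF-κB pathway components had 23.7 ± 0.516 calls after IFNγ and 21.5 ± 1.05 after vehicle (SD, n = 6 each; exact permutation test, p = 0.00926, adjusted p = 0.102), at percentile 92.1 of random lists. The full lists turned the difference of 2.17 to -5.67 (exact permutation test, p = 0.315). Differences for the remaining lists were 0.333 regions for MHC class II, 0.833 for checkpoint ligands, 0.167 for NF-κB target genes, -1.5 for melanocyte lineage, 1.83 for dedifferentiation and AP-1, -0.333 for leukocyte markers, 0.333 for skin and stroma markers and 0.667 for housekeeping genes, with exact permutation p-values from 0.231 to 1. Libraries of one guide were more alike within a treatment than between treatments by 0.0150 in the Jaccard index (0.683 against 0.668, one-sided exact permutation test, p = 0.037). With the full lists the difference did not pass (0.0232, exact permutation test, p = 0.185), and it lost its call in 6 of 12 runs with 1 library left out.

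**Figure D2:**
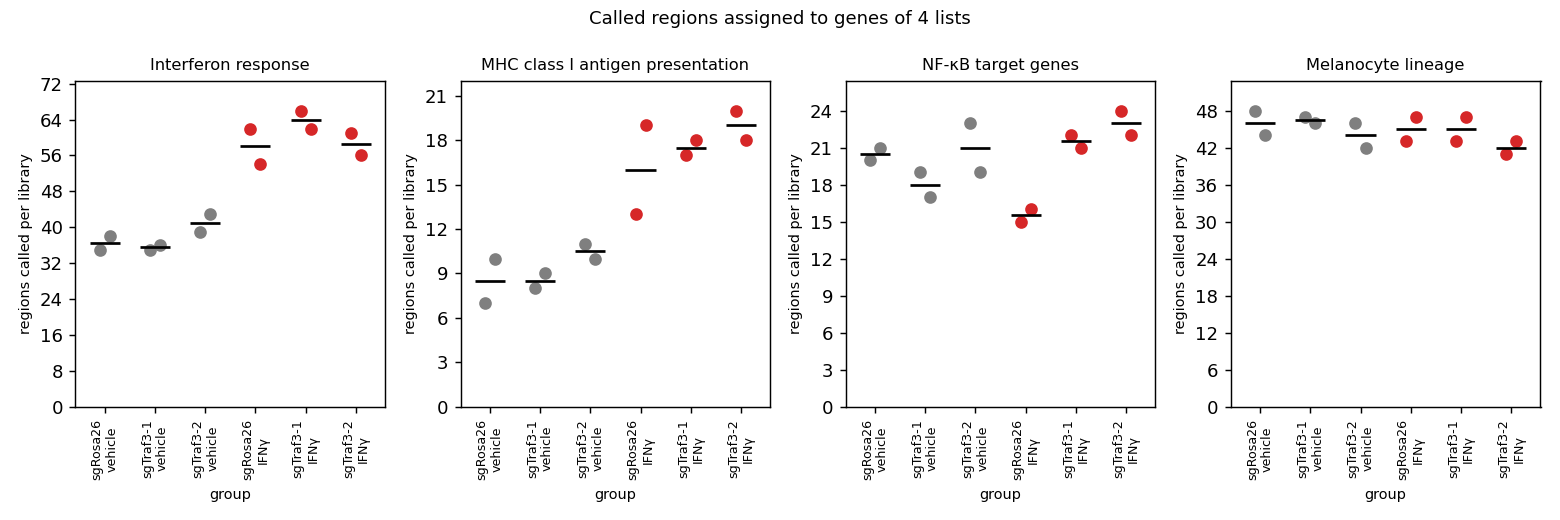
Points give the number of called regions near the genes of 4 lists in each library, bars the mean of the 2 libraries of a group, red points IFNγ and grey points vehicle. Interferon response calls lie between 54 and 66 after IFNγ and between 35 and 43 after vehicle, and MHC class I calls between 13 and 20 and between 7 and 11.

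The IFNγ response was then taken within each genotype. In sgTraf3 cells (4 against 4 libraries) 76 regions were gained and 31 lost; in sgRosa26 cells (2 against 2) 438 were gained and 463 lost, where no split can give a p under 0.333. The other 2 splits of those 4 sgRosa26 libraries separated 672 and 683 regions, against the real 901. The full lists gave 56 gained and 54 lost in sgTraf3 cells and 101 gained and 1808 lost in sgRosa26 cells, so the balance of gains and losses changed with list length. Separated under both settings were 27 gained and 3 lost regions in sgTraf3 cells, and 33 gained and 150 lost in sgRosa26 cells. In sgTraf3 cells the 76 gained regions included those at the end of H2-K1, a classical MHC class I gene, and 830 bp from Bcl3, an NF-κB regulator gene. That Bcl3 region was present in all 8 full sgTraf3 lists and in 5 full vehicle lists, so its gain was a shift across the rank limit. The H2-K1 region was present in 2 full vehicle lists. In sgRosa26 cells the 438 gained regions included another near Bcl3, 5970 bp from its end, and regions of Irf1, Irf9, Cxcl10, Usp18 and Parp14. Irf1 and Usp18 also had other regions called in all 12 libraries. Interferon response genes were enriched among the gained regions of both genotypes. They made up 10 of 61 against 14 of 931 in sgTraf3 cells (Fisher's exact test, adjusted p = 2.93e-08) and 21 of 379 against 24 of 1850 in sgRosa26 cells (Fisher's exact test, adjusted p = 3.71e-10). Among the 362 regions with enough calls to be separated in both genotypes, 36 were gained in both against 9.40 for independent sets (Fisher's exact test, p = 2.49e-21). Lost in sgRosa26 but gained in sgTraf3 cells were 0 against 7.14 (Fisher's exact test, p = 0.000326). Since 36 of the 41 sgTraf3 gains among these regions were gained in both, the latter value largely restates the former. Agreement of losses was not shown, with 2 lost in both against 1.22 (Fisher's exact test, p = 0.351), and 0 were gained in sgRosa26 but lost in sgTraf3 cells against 1.60 (Fisher's exact test, p = 0.359). The 36 regions gained in both and the 2 lost in both are by definition those separated over all guides above. The size of the IFNγ difference was not shown to depend on genotype for interferon response genes (1.5 regions more in sgTraf3 cells, exact permutation test, p = 0.8) or for MHC class I genes (1.25 regions, exact permutation test, p = 0.671).

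By complete separation fewer regions followed the genotype than IFNγ, an order that was not tested and that turned when 1 exception was allowed. Of the 17 regions, 9 lay more than 50 kb from a gene end. Over both treatments, 15 regions were called in 8 of 8 sgTraf3 libraries and 0 of 4 sgRosa26 libraries, and 2 showed the converse. One gained region lay inside Traf2, which encodes the TRAF family member that works in complex with TRAF3, 12059 bp from an end of the gene (chromosome 2, 25533862 to 25534881). It was present in 8 of 8 sgTraf3 and 0 of 4 sgRosa26 full lists as well, whereas the region at the Traf2 end (25546611 to 25547804) was called in all 12 libraries. Other gained regions lay 26501 bp from an end of Eif2ak3, the gene of the stress kinase PERK (chromosome 6, 70877823 to 70878740), inside Frmpd1 (chromosome 4, 45191841 to 45192667), 4661 bp from Amn1, 42637 bp from Otp, at Atp5e, and 10025 bp from Gzmb, the granzyme B gene (chromosome 14, 56272359 to 56273076). Gzmb stands on the leukocyte list, whose calls as a whole differed by 0.125 regions (exact permutation test, p = 1). The remaining 8 gained regions lay more than 50 kb from an end of any gene used here, which leaves out most non-coding genes. Among them were regions 247194 bp from an end of Rad51b and inside it (chromosome 12, 79600161 to 79601066) and 264095 bp from Eea1 (chromosome 10, 96309613 to 96310275). The lost regions lay at Gca and inside Epb41l2.

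Per region this pattern has p = 0.00202 (Fisher's exact test); 0 of 5231 regions passed Benjamini-Hochberg adjustment, 102 had an unadjusted p under 0.05. Adjusted over the list alone, the Traf2 and Gzmb regions passed (Fisher's exact test, adjusted p = 0.0283 and 0.00606), and none did in the other 9 of the 11 lists. The Gzmb region was present in 2 full sgRosa26 vehicle lists. The full lists gave 12 gained and 4 lost, with 8 gained and 0 lost in common. With the 9 longest lists, chosen after seeing the data, 56 were gained and 35 lost. Splitting the libraries by list length alone, the 8 longest against the 4 shortest, separated 11 regions, against 17 for genotype.

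No list differed between genotypes past the threshold. The differences, sgTraf3 minus sgRosa26, were 2.88 regions for NF-κB target genes (exact permutation test, p = 0.107), 1.75 for checkpoint ligands (p = 0.187), 1.62 for MHC class I (p = 0.244), 2.5 for interferon response (p = 0.307), and 0.5 for NF-κB pathway components (p = 0.480). They were -0.125 for MHC class II, -1.12 for melanocyte lineage, 2.12 for dedifferentiation and AP-1, -0.750 for skin and stroma markers and -1.25 for housekeeping genes, all by the exact permutation test. With the 9 longest lists, interferon response and checkpoint ligand calls were higher in sgTraf3 cells by 7.17 and 4.08 regions. That setting leaves sgRosa26 IFNγ replicate 1 as the only sgRosa26 library after IFNγ, so no p-value is given. With regions within 1 kb of a gene end NF-κB target calls were higher by 2.12 (exact permutation test, p = 0.0311, unadjusted). The Jaccard index within a genotype was 0.681 and that between genotypes 0.678, a difference that did not pass (one-sided exact permutation test, p = 0.351).

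Within one treatment, the genotype separated 114 gained and 126 lost regions after vehicle and 106 gained and 135 lost after IFNγ (4 against 2 libraries each). Other splits of the same libraries reached 283 and 449 regions, and the full lists gave 62 gained with 353 lost and 180 gained with 65 lost. With 4 against 2 libraries a single region cannot reach the threshold (smallest p by Fisher's exact test, 0.0667). After IFNγ the list genes with a gained region were H2-K1, H2-Q4, H2-DMa, Ier3, Il34, Traf2 and Gzmb, and no list was enriched past the threshold (Fisher's exact test, smallest adjusted p = 0.132). Of these genes, H2-DMa, Ier3, Il34 and Traf2 also had other regions called in all 12 libraries. Both sgTraf3 guides were compared over treatments (4 against 4 libraries), with 15 regions called in every sgTraf3-1 and no sgTraf3-2 library, 13 the other way round, and 33 and 8 in the full lists; other splits reached 107.

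**Figure D3:**
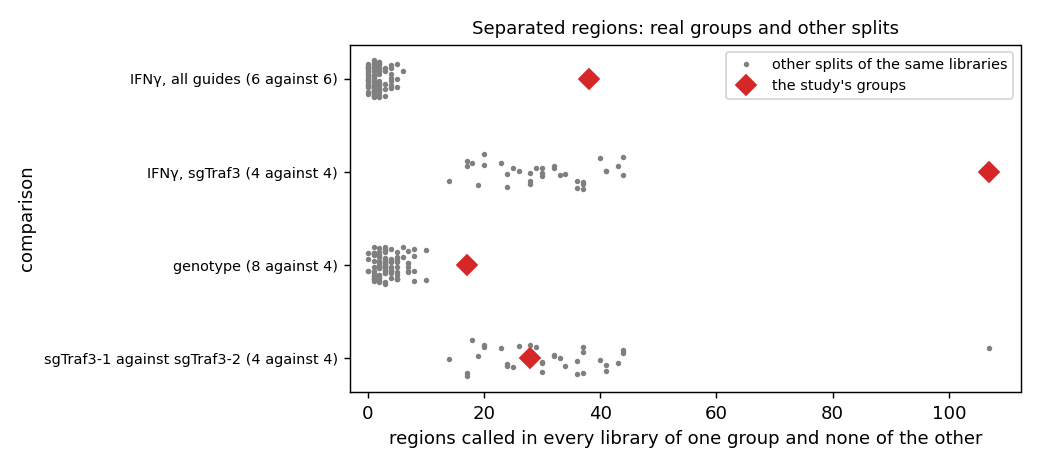
The horizontal axis gives the number of regions called in every library of one group and none of the other; red diamonds are the study's groups and grey points other splits of the same libraries into groups of the same sizes. The real counts are 38, 107, 17 and 28 regions, and the highest other splits shown give 6, 44, 10 and 107. For IFNγ over all guides and for genotype, 100 splits were drawn of 462 and 495 possible. A genotype-sized split by list length, not drawn, gave 11.

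Genes of MHC class I and PD-L1, the subjects of the series title, were then examined singly. The end of H2-K1 (chromosome 17, 33999840 to 34000754) was called in 4 of 4 sgTraf3 IFNγ libraries and in 0 of the other 8 (Fisher's exact test, p = 0.00202, unadjusted). In the full lists it was present in those 4, in 2 sgTraf3 vehicle libraries and in 0 sgRosa26 libraries. The end of H2-Q4 was called in 7 of 8 sgTraf3 and 0 of 4 sgRosa26 libraries (Fisher's exact test, p = 0.0101, which did not pass adjusted over the list alone, smallest adjusted p = 0.121). H2 genes have close relatives in the same cluster, and reads shared between them leave both assignments uncertain. For Cd274, which encodes PD-L1, the region at the gene end (chromosome 19, 29361543 to 29362363) was called in 0 IFNγ and 2 vehicle libraries (Fisher's exact test, p = 0.455), both of them sgTraf3. The full lists held it in 7 of 8 sgTraf3 and 0 of 4 sgRosa26 libraries. A region 6272 bp away (29354906 to 29355835, inside Plgrkt) was called in 3 IFNγ and 3 vehicle libraries, 6 of 8 sgTraf3 and 0 of 4 sgRosa26 (Fisher's exact test, p = 0.0606). It was present in 1 full sgRosa26 vehicle list. In all, 8 regions were called in every sgTraf3 IFNγ library and in no other, and 3 in every other library and in no sgTraf3 IFNγ library. Besides H2-K1 the gained ones lay near Tlr2, Rph3al, Edem1, Parva, P3h1, Sptbn1 and an uncharacterised locus in Anxa9, and the lost ones near Samd5, Dtwd2 and Mvb12b. The full lists gave 10 gained and 3 lost, with 1 gained region, near Edem1, and 0 lost in common. Each other gained region was present in the full list of at least 1 further library, so for these the rank limit was not ruled out.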

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

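The tests in this part were chosen after the results were seen, except the comparison of list calls between genotypes itself and its adjusted p. Its place among random lists and the settings named as planned are further exceptions.

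The IFNγ effect on calls near NF-κB target genes differed between genotypes by an unadjusted p alone, in a test that any effect of genotype can move. The sgTraf3 libraries had 22.2 ± 1.26 calls after IFNγ and 19.5 ± 2.52 after vehicle (SD, n = 4 each), and the sgRosa26 libraries 15.5 ± 0.707 and 20.5 ± 0.707 (SD, n = 2 each), a difference between the effects of 7.75 regions (exact permutation test, p = 0.0222). Of the 20 genes with a region, 12 moved in that direction and 3 against it. Among the planned settings, the difference no longer passed when regions within 1 kb of a gene end were counted. With 1 library left out it ranged from 6.92 to 8.92 regions and did not pass in every run. The adjusted p over the 33 list tests was 0.183, so a difference of this size among that many lists may be chance. Whether peaks close to the rank limit made it cannot be told from these values: among the top 5693 peaks of each list the difference was -1.0 regions, as peaks near the limit would need, but in the full lists, which have no such limit, it stayed at 7.75 regions without exceeding the spread between libraries (exact permutation test, p = 0.418). A real effect of TRAF3 loss on weakly accessible NF-κB target sites stays open, and was not tested separately.

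In sgTraf3-2 IFNγ replicate 1, 4 regions near leukocyte marker genes were called, against 3 in each of the other IFNγ libraries. In sgRosa26 vehicle replicate 1, 5 regions near skin and stroma marker genes were called, against 2 to 3 in the other vehicle libraries. Both stood apart from their group by more than the critical gap, 26 groups of values were looked at in this way, and chance alone would single out about 1.3. These counts are small whole numbers with ties. With the other leukocyte counts all at 3, any single different count would stand apart, so the chance figure may be too low here.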

How the results depend on the processing

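One setting, the 9 longest lists, was chosen after seeing the data; the other settings were planned. The IFNγ difference in interferon response and MHC class I calls kept its direction under each setting run and kept an unadjusted p under 0.05 (exact permutation test) under each except the full lists; adjusted over 33 tests, the main values did not pass. The differences were 14.2 to 25 and 2.33 to 9.33 regions. Read depth was unknown, list length stands in for it only in part, and the causes of the changes below were not tested except where fewer libraries or a looser rule admits more regions by construction.

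With the full lists, separated regions numbered 1909 for IFNγ in sgRosa26 cells and 415 for genotype after vehicle. The Jaccard difference by treatment was 0.0232 (exact permutation test, p = 0.185) and that by genotype -0.0112. The lists past an unadjusted p of 0.05 went from 3 to 0 for IFNγ and from 1 to 0 for the difference of effects between genotypes. IFNγ list differences became 14.5 for interferon response and 6.0 for MHC class I, and turned to -0.167 for MHC class II, -1.83 for checkpoint ligands, -5.67 for NF-κB pathway and -4.83 for NF-κB targets. Differences of effects between genotypes turned to -0.750 for MHC class I, 3.25 for checkpoint ligands, 1.25 for NF-κB pathway and 6.75 for melanocyte lineage, and NF-κB targets stayed at 7.75 (exact permutation test, p = 0.418).

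With the top 5693 peaks of each list, 528 regions were separated by IFNγ in sgRosa26 and 68 in sgTraf3 cells, and the lists with a difference of effects fell from 1 to 0. The IFNγ difference of NF-κB pathway lost its call (1.17 regions, exact permutation test, p = 0.315). That of melanocyte lineage turned to 0.5, the genotype differences of interferon response to -1.25 and MHC class II to 0.125, and the differences of effects to 1.75 for NF-κB pathway, -1.0 for NF-κB targets and 3.0 for melanocyte lineage. Counting regions within 1 kb of a gene end, 1 list passed for genotype in place of 0 (NF-κB targets, 2.12 regions, exact permutation test, p = 0.0311). For the difference of effects, NF-κB targets lost their call (3.25 regions, exact permutation test, p = 0.0889) and MHC class II gained one (1.25 regions, exact permutation test, p = 0.0444). IFNγ differences were -0.167 for MHC class II and 1.33 for NF-κB pathway (exact permutation test, p = 0.204), genotype differences 0.375 for MHC class II, -0.625 for NF-κB pathway and 0.5 for melanocyte lineage, and differences of effects -2.0 for interferon response and 0.5 for melanocyte lineage. With one score threshold for every list, the genotype difference in peak number was 155 peaks. A 50% overlap of narrowed peaks left each count of separated regions within 1.5 times.

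With 1 exception allowed, separated regions numbered 223 for IFNγ over all guides, 1072 for IFNγ in sgTraf3, 237 for genotype over both treatments, 879 after vehicle, 875 after IFNγ, 845 for guide and 267 for sgTraf3 with IFNγ alone. Fisher's exact test with Benjamini-Hochberg adjustment passed 0 regions for IFNγ (123 unadjusted) and 0 for genotype (102 unadjusted). With the 9 longest lists the counts were 135 for IFNγ over all guides, 399 in sgTraf3 and 91 for genotype. The IFNγ difference of NF-κB pathway lost its call (3.5 regions), and the genotype differences of interferon response and checkpoint ligands were 7.17 and 4.08 regions. This setting leaves single libraries in some groups, among them sgRosa26 after IFNγ, so p-values are not given for these differences. IFNγ differences turned to -2.33 for NF-κB targets and 0.5 for melanocyte lineage, and the genotype difference of MHC class II to 0.583.

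Leaving out 1 library loosens the rule and so raises the counts: 39 to 53 for IFNγ over all guides, 2071 to 3008 in sgRosa26, 153 to 180 in sgTraf3, 376 to 1117 for genotype after vehicle, 378 to 1491 after IFNγ, 60 to 76 for guide, 11 to 29 for sgTraf3 with IFNγ alone and 18 to 36 for genotype over both treatments. The last count was 32 without sgRosa26 vehicle replicate 2, 36 without sgRosa26 IFNγ replicate 1 and 34 without sgRosa26 IFNγ replicate 2. In sgTraf3 it passed 1.5 times the full count without sgTraf3-1 vehicle replicate 2 (167), sgTraf3-1 IFNγ replicate 2 (169), sgTraf3-2 IFNγ replicate 1 (169) or sgTraf3-2 IFNγ replicate 2 (180). For sgTraf3 with IFNγ alone it did so without any of the 6 IFNγ libraries (20 to 29), and for the guide and the comparisons with 2 sgRosa26 libraries whichever library was left out. The Jaccard difference by treatment ranged from 0.00284 to 0.0308 and lost its call without sgRosa26 vehicle replicate 1 (0.00851) or 2 (0.0104), sgTraf3-2 vehicle replicate 1 (0.00284) or 2 (0.00396), or sgTraf3-1 IFNγ replicate 1 (0.00828) or 2 (0.00990). That by genotype ranged from -0.00745 to 0.0104, turning without sgRosa26 IFNγ replicate 2. The peak number difference ranged from -5364 to -1984 for IFNγ, reaching p = 0.0463 (exact permutation test) without sgTraf3-1 vehicle replicate 2 (-5076), and from -2857 to 2214 for genotype. The lists with a difference of effects ranged from 0 to 1: NF-κB targets had p = 0.0667 (exact permutation test) without sgRosa26 vehicle replicate 2 (7.25 regions), sgRosa26 IFNγ replicate 1 (7.25) or sgRosa26 IFNγ replicate 2 (8.25). Other differences that turned ranged from -0.5 to 0.833 for NF-κB targets by IFNγ, from -0.375 to 0.125 for MHC class II by genotype, and, for the effects between genotypes, from -2.50 to 0.5 for checkpoint ligands, -1.75 to 4.25 for MHC class I, -2.50 to 5.50 for interferon response and -2.75 to 1.25 for melanocyte lineage.

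Replicate numbers did not pair the libraries: correlations of deviations between same-numbered libraries lay between -0.033 and 0.086 over 15 pairs of groups, with 0 over 0.1. A replicate block changed no call (3 lists for IFNγ, with a difference of 22.5 for interferon response). The motif search was not run.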

Other observations

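The tests of other splits and of the rank limit were chosen or run after the results they bear on were seen; those of list length were written before.

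Some regions of melanocyte, AP-1, interferon response and NF-κB pathway genes were called under all conditions. Over all 27731 regions, 5867 were called in all 12 libraries, and no test compared the lists with that share. Of 95 regions near melanocyte lineage genes, 31 were called in all 12 libraries and 31 in none, those called in all 12 including regions of the lineage regulator genes Mitf, Pax3 and Tfap2a and of the pigment genes Tyr, Tyrp1, Dct, Pmel, Mlana, Mc1r and Slc45a2. Of 67 regions of the dedifferentiation and AP-1 list, 15 were called in all 12 and 15 in none, the former including regions of Jun, Junb, Jund, Fos, Fosb, Fosl2, Atf3 and Zeb1. Of 111 interferon response regions, 19 were called in all 12 libraries and 21 in none, the former at 14 genes such as Stat2, Socs1, Socs3, Ifngr1, Jak1, Cxcl11, Irf1 and Usp18. Among NF-κB pathway genes, 10 of 55 regions were called in all 12 and 13 in none, the former including regions of Map3k14, Nfkb1 and Cyld.

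The regions gained after IFNγ held up as a set against chance and list length, and 12 of the 36 against the rank limit. Of 100 splits of the 12 libraries, 1, the real one, separated as many as 38 regions. The highest other split drawn gave 6, which argues against chance. Splitting by list length, the 6 longest against the 6 shortest, separated 4 regions, which argues against list length as the only source. Of those 6 shortest lists, 4 were IFNγ libraries. Of the 36 gained regions, 12 were in no full vehicle list, so the rank limit alone cannot have made the whole pattern. The other 24 were present below the limit in at least 1 full vehicle list, so for them the rank limit was not ruled out. A response of these cells to IFNγ is then a hypothesis that remains. Reads shared between related GTPase genes, the unknown read depth and any other difference between the IFNγ and vehicle libraries were not tested. In sgTraf3 cells alone, 1 of 35 splits, the real one, reached the count of 107 regions and the highest other gave 44. A share of 1 in 35 is the smallest this test can give, so it argues against chance without excluding it.

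For the 17 regions separated by genotype, 1 of 100 splits, the real one, gave as many and the highest other split drawn gave 10. The 8 longest lists against the 4 shortest separated 11 regions, and 2 of those 4 shortest were sgRosa26 libraries, so list length and genotype cannot be told apart for part of the count. Against the rank limit as the only source stand 8 of the 15 gained regions, which were in no full sgRosa26 list. Separated regions lay more than 50 kb from a gene end in 9 of 17 cases (52.9%), against 303 of 1735 other regions called in 4 or 8 libraries (17.5%). This comparison was made because the distances had been seen, so it supports no conclusion about a class of sites. All sgRosa26 libraries carry the same guide, and a property of that cell population other than TRAF3 stays open and was not tested.

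Between the sgTraf3 guides, 23 of 35 splits separated as many as the real 28 regions and the highest other gave 107, so chance cannot be excluded. The split that gave 107 follows IFNγ treatment. For sgTraf3 with IFNγ alone, 2 of 100 splits gave as many as 11 regions, the real one included, and the highest other gave 16. Most of those splits mix treatments, so they argue against chance only for a group that takes in the response to IFNγ. Of the 15 splits that take 4 IFNγ libraries against the other 8, 4 gave as many, the real one included, with 16 as the highest other; they are too few for a share under 0.05, and a dependence of the set on genotype was not shown.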
